A study of Mus musculus with 12 samples.

How the data were processed

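RNA was profiled from midbrain dopaminergic neurons of C57BL/6 mice in 2 regions, the substantia nigra pars compacta (SNpc) and the ventral tegmental area (VTA). The labels describe the samples as TRAP samples. TRAP is read here as translating ribosome affinity purification, in which a tagged ribosomal protein is made in a chosen cell type and pulled down from tissue, so that the RNA bound to the ribosomes of those cells is enriched over that of their neighbours. Per the labels' protocols, cDNA was made from a very small RNA input with the NuGEN Ovation V2 kit, sheared, turned into TruSeq libraries and read from one end on an Illumina HiSeq instrument, with libraries multiplexed in pairs. This whole-transcript amplification does not mark the strand, and it copies RNA before the fragmentation step, so the number of reads of a gene depends on how evenly long transcripts were copied as well as on their abundance. The lane, the day and the animals of each library are not given in the sources used here.

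The values are counts of reads per gene as deposited by the authors, whole numbers with no normalization, for 23079 genes named by Entrez identifier and in 12 columns, 6 per region. Reads were aligned with TopHat2 2.0.8 to build mm10, per the submitters' processing notes. The counting program, the annotation release, the strand setting and any filter are not given in the sources used here. Reads of genes that overlap another gene or that have a near-identical paralog may therefore have been split in either way, and only some such genes are named as uncertain. Others named below also share exonic sequence with another transcript, among them Slc18a2, Satb1, Tpbg, Cerkl, Neurod1, Onecut1, Cacna1d, Itpr1, Pclo, Slc1a2 and Cox5a. Of the identifiers, 23008 matched a RefSeq gene table, which gave current symbols, and 20945 had a transcript length from GENCODE. Coordinates are on mm10. No column lacked a sample, and 0 lines of the table named no gene. Mitochondrially encoded mRNAs, planned as a library measure, were not analysed here.

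Before replicates were averaged, all pairs of columns within a region were compared. SNpc columns 4 and 5 held identical counts for every gene, as did VTA columns 2 and 3, whereas all other pairs of a region differed with chi-square values per gene of 46.8 to 162. Each identical pair was counted as 1 library, named SNpc library 4 and VTA library 2. The comparison therefore had 5 libraries per region, 10 in all, and not the 12 that the planned design had assumed. The tests, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. The 12 columns as deposited were run as an alternative. Total counts ran from 62356964 to 81393907 per library. Nothing in the labels says that the libraries of a region came from separate animals, so p-values measure the spread between these libraries, which may be technical.

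Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by filterByExpr with the region as the group, which left 15685, library sizes were scaled by trimmed mean of M values (TMM), and a robust quasi-likelihood F test compared the regions with no covariate. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Log2 fold changes are SNpc minus VTA. Mean log2 CPM values used a prior count of 2. Standard errors are those of the log2 fold change. Mean CPM values are TMM-scaled and given ± SD.

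A set of 42 gene lists was written from general knowledge of dopaminergic neurons and their neighbours, and 40 of them had at least 3 tested members and entered the list test. Each list is described by its members called over all genes tested and by the number called when p-values were adjusted over the list alone. Camera from limma 3.58.1, with a preset correlation between genes of 0.01, compared each list with the other genes, with Benjamini-Hochberg adjustment over the 40 lists. Camera with a correlation estimated from the data, and fry, which asks only whether the genes of a list move on balance in one direction, were run beside it. A family of 15 library measures (total count, genes with a count, share of the 100 most abundant genes, share of ribosomal protein genes and the mean log2 CPM of each of 11 lists of other cell types) was compared by two-sided exact permutation tests of the difference of means, which with 5 libraries against 5 cannot give a p under 0.00794.

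The genes named follow a rule. They are 13 dopaminergic, regional and study genes, the 10 genes with the largest change in each direction among called genes with a mean log2 CPM of at least 3 and no overlap of the groups, up to 6 members of each list (the 4 with the smallest p and the 2 most abundant), and genes in which 1 library stood apart. The ranking by change left out genes listed under placeholder symbols (Gm with digits, ending in Rik or starting with LOC). Members of 3 lists added after the results were seen are named as such. Single values of some list members are not reported here.

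Transcript length was checked because of the amplification step. A length was found for 94.3% of the tested genes. Spearman correlations across genes used 12413 of them, and genes are not independent replicates. For a corrected fit, each library's log2 CPM was regressed on splines of log2 transcript length and GC content with 4 degrees of freedom, and the fitted trend entered the edgeR fit as an offset. In one version the TMM scale of each library was kept, and in the other the scale was refitted with the trend. The version with the scale kept was written after the other had been run, because the refitted scale had moved the median log2 fold change of all genes from -0.04 to 0.09. Both are reported because they give different counts.

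The methods were tested on simulated data. With 15499 genes drawn from the real means and library sizes and 200 genes changed, the edgeR test recovered 26.9% of 1.5-fold, 59.7% of 2-fold and 90.9% of 4-fold changes, and 11 of its 129 calls were false. Camera called 0 of 40 unchanged lists, but the simulated genes varied independently of each other. This says nothing of correlated lists, and estimated correlations in the real lists reached 0.872, for ribosomal proteins. When a transcript length trend was added to 15525 simulated genes, 2873 of 3011 calls were false without a correction and 7 of 119 with it. That correction used length alone and recovered 49.3% of 2-fold changes, against 61.2% without it. The added trend was linear in log2 length and equal in all SNpc libraries, with rho of -0.725 against -0.473 in the real data. Splines can fit such a form, so the simulation cannot show whether the correction removes real differences that follow length.

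The other settings fixed at the start were DESeq2 1.42.0, limma-voom, other scalings, other filters, the replicate number as a block, a covariate made of glial markers, thinning to the smallest total, a test against a 1.5-fold change and leaving out each library. The glial covariate was the mean log2 CPM of the astrocyte, oligodendrocyte, oligodendrocyte precursor and microglial markers. It was lower in SNpc, and its correlation with region was -0.562. The length corrections, the 12 columns as deposited and leaving out SNpc library 4 together with VTA library 1 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.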

Results

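Dopaminergic neurons of the SNpc degenerate earlier and more completely in Parkinson disease than those of the adjoining VTA, and the series compares the RNA of both populations in the mouse. After the 2 pairs of identical columns had been counted once each, 5 SNpc and 5 VTA libraries remained. Those pairs differed by less than the sampling noise, with 0 genes at different counts. Total counts were 65959443, 62951005, 64777777, 63288612 and 64364322 in SNpc libraries 1, 2, 3, 4 and 6. In VTA libraries 1, 2, 4, 5 and 6 they were 81393907, 65272991, 62356964, 69465336 and 69083463. Of the 23079 genes listed, 3036 had no count in any library. The first principal component carried 36.5% of the variance and placed all SNpc libraries on one side and all VTA libraries on the other, with SNpc library 4 nearest to the VTA side.

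The libraries of the 2 regions differed broadly. Of 15685 genes tested, 2793 were higher in SNpc and 3203 were higher in VTA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 5996 in all. Large differences lay mostly on the VTA side, where 1605 genes were at least 2-fold higher, against 126 in SNpc. RNA of other cells, treated below, may contribute to this imbalance. The groups' CPM values did not overlap for 4034 of the called genes, and 26.6% of all tested genes had separate groups, where chance gives 0.794%. The biological coefficient of variation was 39.6% and the median standard error of a log2 fold change 0.19. The genes higher in SNpc made up 46.6% of the calls. They made up 63.6%, 3586 genes against 2050 genes higher in VTA, when a transcript length and GC trend was removed and the library scale refitted. With glial markers as a covariate the genes higher in SNpc fell to 1798. Against a minimum change of 1.5-fold, 94 genes higher in SNpc and 1146 genes higher in VTA passed the test.

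**Figure D1:**
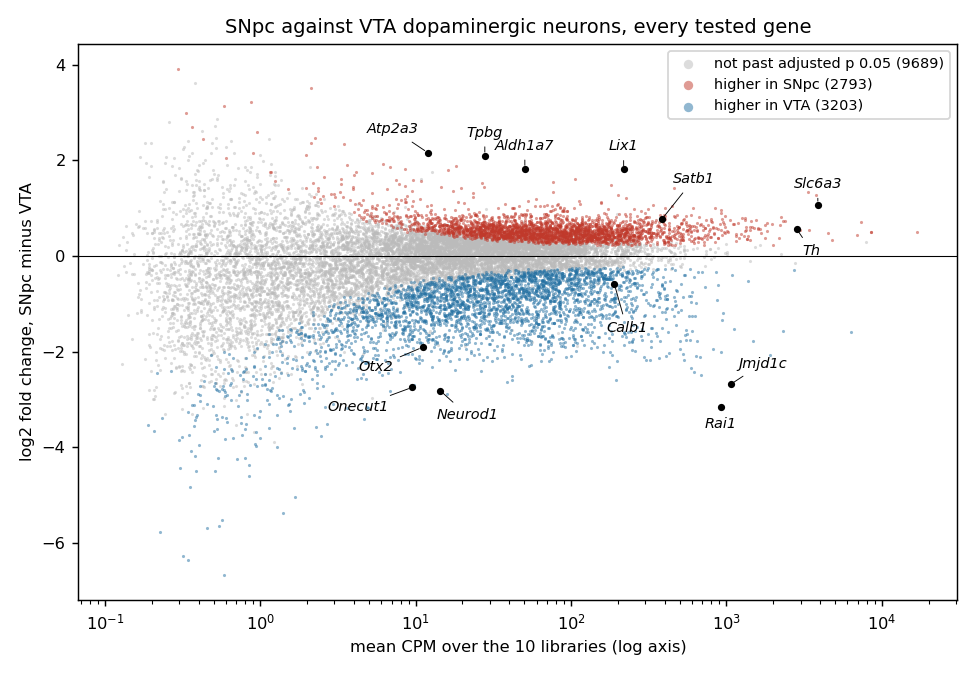
Log2 fold change (SNpc minus VTA) of every tested gene against its mean CPM over the 10 libraries on a log axis, with genes higher in SNpc in red (2793), genes higher in VTA in blue (3203) and all others in grey. Called changes reach further from 0 on the VTA side, with 1605 genes at least 2-fold higher there against 126 in SNpc.

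Genes that define dopaminergic neurons were more abundant in SNpc. Of 21 dopaminergic identity genes, 18 were higher in SNpc and 0 in VTA, with the same 18 adjusted over the list alone and a median log2 fold change of 0.68. The list was called by camera (adjusted p = 6.67e-09), with adjusted p = 0.291 with an estimated correlation. Slc6a3, the plasma membrane dopamine transporter (Entrez 13162, mm10 chromosome 13, 73536128 to 73578672), stood at 5256 ± 635 CPM in SNpc and 2499 ± 580 in VTA (SD, n = 5 each). Its log2 fold change was 1.07 with a standard error of 0.14 (edgeR adjusted p = 4.15e-05). Th, the rate-limiting enzyme of dopamine synthesis (Entrez 21823, chromosome 7, 142892779 to 142899995), was 3381 ± 564 CPM against 2280 ± 394, a log2 fold change of 0.57 ± 0.13 (SE, edgeR adjusted p = 0.00246), although its groups overlapped. The decarboxylase Ddc (0.80), the vesicular monoamine transporter Slc18a2 (0.77), gamma-synuclein Sncg (1.06) and the transcription factor Foxa1 (0.96) rose likewise on the log2 scale. Nr4a2 and Pitx3, which specify these neurons, had log2 fold changes of 0.40 and 0.79, and both calls ended with glial markers as a covariate, that of Pitx3 also with the correction for length alone. Pitx3 shares exonic sequence with Elovl3 on the opposite strand.

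Known regional markers followed their region in most cases. Of 14 genes described before as higher in SNpc dopaminergic neurons, 12 were higher in SNpc and 0 in VTA, with 12 adjusted over the list alone. The median log2 fold change was 1.00 (camera adjusted p = 1.46e-12, adjusted p = 0.139 with an estimated correlation). Sox6, a transcription factor that marks SNpc neurons (Entrez 20679, chromosome 7, 115470872 to 116040776), was 98.2 ± 12.9 CPM in SNpc and 51.1 ± 4.56 in VTA, a log2 fold change of 0.94 ± 0.11 (SE, edgeR adjusted p = 7.79e-06). The retinaldehyde dehydrogenase Aldh1a1 (Entrez 11668, chromosome 19, 20492583 to 20643463) was 2995 ± 464 against 1791 ± 151 CPM, a log2 fold change of 0.74. Its neighbour Aldh1a7 (chromosome 19, 20692953 to 20727556) was 78.6 ± 18.0 against 22.2 ± 7.15 CPM, a change of 1.82, but the paralogs are similar in sequence and how shared reads were assigned is not known. The growth factor Fgf1 (1.49), the secreted protein Ndnf, listed as A930038C07Rik (1.61), and the protease inhibitor Serpine2 (1.27) were also higher in SNpc.

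Satb1 and Zdhhc2, a chromatin organiser and a palmitoyltransferase that the study itself singled out, were both higher in SNpc. Satb1 (Entrez 20230, chromosome 17, 51736187 to 51833290) was 484 ± 61.8 CPM in SNpc and 284 ± 30.7 in VTA, a log2 fold change of 0.77 ± 0.10 (SE, edgeR adjusted p = 3.02e-05). Zdhhc2 (Entrez 70546, chromosome 8, 40423485 to 40489592) was 105 ± 9.90 against 57.4 ± 8.01 CPM, a change of 0.87 ± 0.11 (SE, edgeR adjusted p = 2.16e-05). Its exons overlap Cnot7 on the opposite strand, so its count is uncertain. Those of Satb1 overlap Gm36931 on the same strand and Gm6934 on the opposite strand, so the same holds for Satb1. Both of 2 were called adjusted over the list alone. Since the study chose them on these samples, their direction is not independent evidence.

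The genes with the largest rise in SNpc were not dopaminergic synthesis genes. Atp2a3, a calcium pump of the endoplasmic reticulum (chromosome 11, 72961169 to 72993043), led with 19.5 ± 5.32 against 4.36 ± 2.67 CPM, a log2 fold change of 2.16 ± 0.46 (SE, edgeR adjusted p = 0.00246). The membrane glycoprotein Tpbg (2.10), the cell surface protein Cd24a (1.89), the cytochrome Cyp4v3 (1.81), Lix1 (1.81), the small GTPase Rasl11b (1.80), Srpx2 (1.58), the galactose enzyme Galm (1.58) and D19Ertd737e (1.54) completed the 10 with Aldh1a7. Ndnf (1.61) was left out of this ranking only because it is listed under a symbol ending in Rik. Lix1 was the most abundant of them, at 339 ± 33.9 CPM against 96.7 ± 27.1.

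VTA markers were more divided. Of 19 tested, 13 were higher in VTA and 2 in SNpc, or 14 and 2 adjusted over the list alone, with a median log2 fold change of -1.33 (camera adjusted p = 6.20e-05, adjusted p = 0.139 with an estimated correlation). Otx2, a transcription factor of VTA neurons (Entrez 18424, chromosome 14, 48656781 to 48667644), was 4.66 ± 0.387 CPM in SNpc and 17.5 ± 3.45 in VTA, a log2 fold change of -1.91 ± 0.19 (SE, edgeR adjusted p = 1.55e-06). It overlaps an opposite-strand transcript, Otx2os1. The peptide genes Adcyap1 (-2.21) and Grp (-1.72) and lipoprotein lipase Lpl (-2.04) were higher in VTA as well. Calb1, a calcium buffer and a classical VTA marker (Entrez 12307, chromosome 4, 15881264 to 15906709), was 152 ± 40.7 CPM in SNpc and 229 ± 55.1 in VTA, with overlapping libraries. Its log2 fold change of -0.59 ± 0.22 (SE) did not pass the test (edgeR adjusted p = 0.0512), and over the alternatives its adjusted p ran from 0.00474 to 0.321. The markers Cadps2 and Etv5 were higher in SNpc, each with a log2 fold change of 0.41. Both calls ended with glial markers as a covariate, and that of Etv5 also without SNpc library 1.

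**Figure D2:**
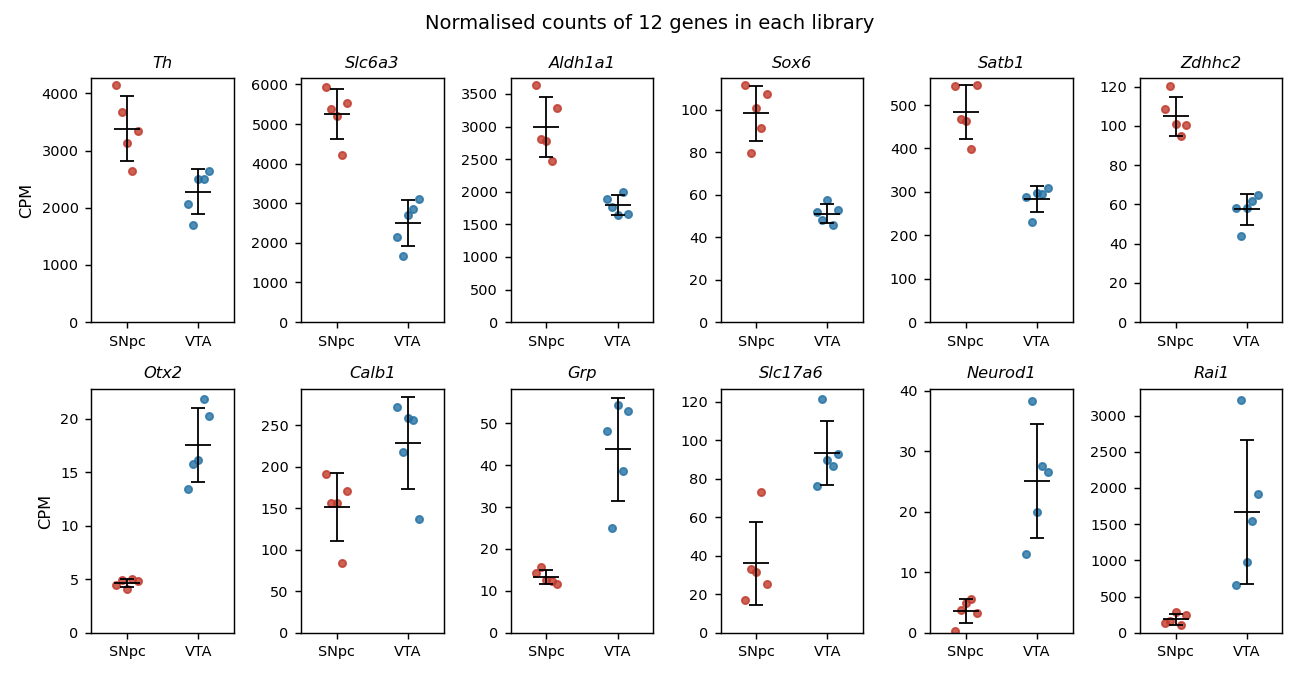
TMM-scaled CPM of 12 genes in each of the 5 SNpc (red) and 5 VTA (blue) libraries on axes that start at 0, with bars for the mean and SD. The groups are separate for all genes shown except Th and Calb1.

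Of the 10 genes with the largest rise in VTA, 4 encode DNA-binding transcription factors. Neurod1, a neuronal differentiation factor (chromosome 2, 79452637 to 79456636), was 25.1 ± 9.41 CPM in VTA and 3.57 ± 2.03 in SNpc, a log2 fold change of -2.81. Its CPM was close to that of its neighbour Cerkl in most libraries, so its count is uncertain. Onecut1 changed by -2.75, and Gli2 and Gli3, the transcription factors of hedgehog signalling, by -2.64 and -2.59. Rai1, a chromatin regulator (chromosome 11, 60104917 to 60199197), showed the largest change of the 10, -3.15 ± 0.50 (SE, edgeR adjusted p = 0.00126), at 1662 ± 993 CPM in VTA and 187 ± 76.7 in SNpc. It overlaps Srebf1 on the opposite strand and its VTA libraries were widely spread. The demethylase-like gene Jmjd1c (-2.68), Cerkl (-2.88), the lipid kinase Dgkk (-2.60), the synaptic adhesion gene Slitrk6 (-2.50) and Prr12 (-2.50) were the others, and the call of Slitrk6 ended with glial markers as a covariate.

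Genes of energy metabolism were higher in SNpc almost without exception. Of 36 complex I subunits, 35 were higher in SNpc and 0 in VTA, as were 38 of 39 subunits of complexes II to V and 13 of 15 glycolytic enzymes. Adjusted over the list alone the numbers were 35, 38 and 15. Median log2 fold changes were 0.59, 0.69 and 0.53, with camera adjusted p = 1.46e-12, 1.65e-16 and 5.57e-09. With an estimated correlation the lists had adjusted p = 0.305, 0.253 and 0.253. Among the respiratory chain genes, Ndufa11 changed by 0.89, Ndufb7 by 0.85, Cox5a by 0.72 and Atp5b, the catalytic ATP synthase subunit, by 0.48. In glycolysis, lactate dehydrogenase Ldhb had the largest change (813 ± 75.6 against 405 ± 39.6 CPM, log2 fold change 1.01) and Gapdh was the most abundant (3399 ± 298 against 2285 ± 158 CPM, 0.57).

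Protein turnover genes showed the same direction. Of 31 proteasome genes, 30 were higher in SNpc and 0 in VTA, or 31 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 8.49e-12, adjusted p = 0.253 with an estimated correlation). Psmd3 changed by 0.82 and Psmc6 by 0.80. Of 75 cytosolic ribosomal protein genes, 43 were higher in SNpc and 0 in VTA, or 54 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.40e-09, adjusted p = 0.496 with an estimated correlation). Without VTA library 1 the count was 22, without VTA library 2 it was 23 and without SNpc library 2 it was 25. It rose to 51 without SNpc library 6, 52 without VTA library 4 and 54 without VTA library 6. Rpl23 (0.64) and Rpl19 (0.52) were among the 43. Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain.

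These lists hold short transcripts, and transcript length moved with the region. Across 12413 genes, Spearman's rho between transcript length and log2 fold change was -0.473, against 0.0281 for GC content. The fifth of genes with the shortest transcripts had a median log2 fold change of 0.38 and the fifth with the longest -0.47. Abundance fell with length in all 5 SNpc libraries relative to the mean of all libraries (slopes of -0.218 to -0.0731 log2 CPM per doubling of length) and rose in all 5 VTA libraries (0.0874 to 0.276, exact permutation p = 0.00794, the smallest possible). After the length and GC trend was removed with the library scale kept, 9 complex I genes, 15 genes of complexes II to V and 9 proteasome genes were still called higher in SNpc. With the scale refitted, 21, 30 and 20 were called. Camera called these 3 lists in both versions, with adjusted p = 0.00491, 1.90e-05 and 0.00148 when the scale was kept. An estimated correlation was tried only without the correction, where it gave the highest values over the alternatives, 0.305, 0.253 and 0.253. The calls of Cox5a and Rpl23 ended with the scale kept and that of Rpl19 in both versions. The ribosomal protein list had 1 gene higher in SNpc and 4 in VTA with a median of -0.05 when the scale was kept, and 8 and 1 with a median of 0.09 when it was refitted. Its direction thus turned in the former version only, and it was called in neither. With the scale kept, glycolysis had 14 called genes, 12 of them called before the correction, and 17 dopaminergic genes and 12 SNpc markers were still called.

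**Figure D3:**
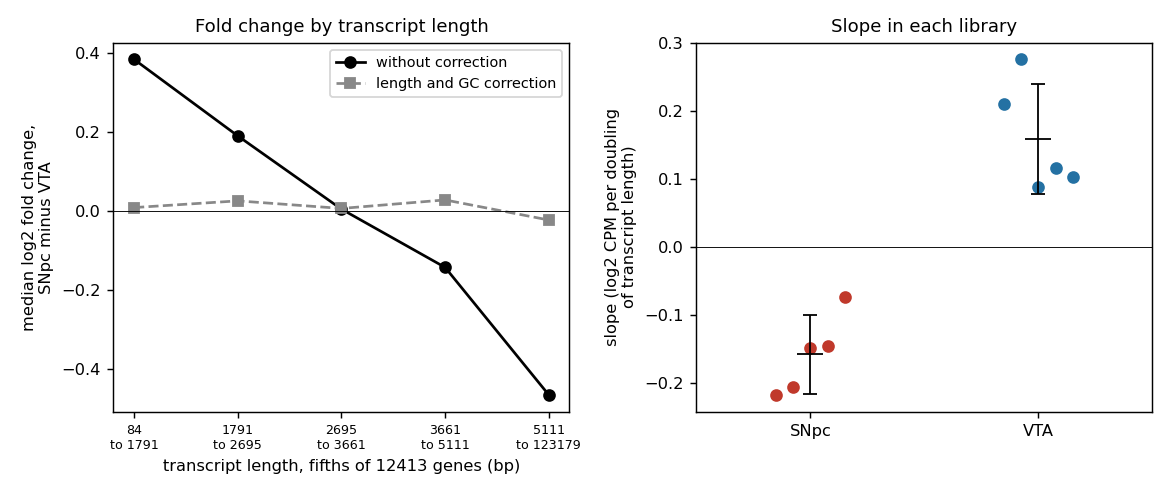
Left, the median log2 fold change (SNpc minus VTA) in 5 equal groups of 12413 genes by transcript length in bp, before (black) and after (grey) the length and GC correction with the library scale kept, and right, the slope of log2 CPM per doubling of transcript length in each library with the mean and SD. Medians fall from 0.38 to -0.47 without correction, and SNpc slopes are all negative and VTA slopes all positive.

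Genes of transmitter release and reception differed in both directions. In the list of 37 synaptic vesicle and release genes, 24 were higher in SNpc and 10 in VTA, the same numbers adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.00386, adjusted p = 0.253 with an estimated correlation). After the length and GC correction with the scale kept, 24 were higher in SNpc and 6 in VTA. Cplx1, a complexin that clamps vesicle fusion, was 4816 ± 579 CPM against 1910 ± 399 (log2 fold change 1.33), and the SNARE protein Snap25 was 9171 ± 797 against 5571 ± 459 (0.72). Pclo, a scaffold of the active zone, went the other way (-1.68). Of 8 nicotinic receptor subunits, 7 were higher in SNpc and 0 in VTA, 7 adjusted over the list alone (median 0.81, camera adjusted p = 6.18e-04, adjusted p = 0.253 with an estimated correlation), including Chrnb3 (0.91), Chrna6 (0.72) and Chrna4 (0.67).

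Most other receptors that changed were higher in VTA. Of 32 monoamine, opioid and cannabinoid receptors, 13 were higher in VTA and 2 in SNpc, or 17 and 2 adjusted over the list alone, with a median of -1.05 (camera adjusted p = 0.00489, adjusted p = 0.253 with an estimated correlation). The cannabinoid receptor Cnr1 (-1.44) and the serotonin receptor Htr2c (-1.08) were higher in VTA, and the dopamine autoreceptor Drd2 in SNpc (0.86). Neuropeptide genes gave 7 of 25 higher in VTA and 1 in SNpc, or 7 and 0 adjusted over the list alone (median -0.61, camera adjusted p = 0.0458, adjusted p = 0.253 with an estimated correlation). The synaptic organiser Cbln4 (-2.29), Cartpt (-1.83) and cholecystokinin Cck (-0.61) were among the 7. The neuropeptide call ended with library totals as the scale, with glial markers as a covariate and without any one of SNpc libraries 1, 2, 3 and 6 or VTA library 4. Neuropeptide receptors (11 of 32 higher in VTA and 3 in SNpc, or 11 and 4 adjusted over the list alone and 7 and 1 with the glial covariate, camera adjusted p = 0.113) did not pass as a list but did after the length and GC correction with the scale refitted (camera adjusted p = 0.0227), and Ntsr1, the neurotensin receptor, was higher in SNpc (0.73).

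Glutamate receptors (10 of 24 higher in VTA and 1 in SNpc, or 11 and 1 adjusted over the list alone, camera adjusted p = 0.0506) and GABA and glycine receptors (7 of 20 in VTA and 3 in SNpc, the same adjusted over the list alone, camera adjusted p = 0.206) did not pass as lists. Both were called without SNpc library 4, and the glutamate receptor list also without VTA library 1 or 5. The 7 GABA and glycine receptors higher in VTA became 4 without SNpc library 3 or 6 and 3 with glial markers as a covariate. The presynaptic glutamate receptor Grm2 (-2.15) and the GABA receptor subunit Gabrq (-1.96) were higher in VTA. After the length and GC correction the glutamate receptor list had 5 genes higher in SNpc and 6 in VTA, and its median turned from -0.32 to 0.09. With the scale refitted there were 8 in SNpc and 3 in VTA, with a median of 0.22. The correction gave 4 GABA and glycine receptors in SNpc and 5 in VTA, or 5 and 5 with the scale refitted.

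Potassium channel genes that passed were more often higher in VTA than in SNpc. Of 52 subunits, 25 were higher in VTA and 7 in SNpc, or 27 and 7 adjusted over the list alone, with a median of -0.62 (camera adjusted p = 0.0122, adjusted p = 0.305 with an estimated correlation). The length and GC correction gave 19 and 10, or 16 and 13 with the scale refitted, and ended the list's call in both versions. With glial markers as a covariate 16 were higher in VTA and 6 in SNpc. The leak channel Kcnk3 was 44.5 ± 8.91 CPM in VTA and 9.82 ± 1.35 in SNpc (log2 fold change -2.18), whereas Kcnip3 (1.01) and the A-type channel Kcnd3 (0.71) were higher in SNpc. Voltage-gated calcium channels (7 of 21 in VTA and 2 in SNpc, the same adjusted over the list alone, camera adjusted p = 0.399) and sodium, HCN and TRP channels (8 of 19 in VTA and 3 in SNpc, the same adjusted over the list alone, camera adjusted p = 0.328) did not pass as lists. After the length and GC correction the balance turned, to 8 calcium channels in SNpc and 4 in VTA (9 and 3 with the scale refitted) and 6 and 3 of the other channels (8 and 2), and the medians went from -0.16 and -0.32 to 0.19 and 0.01. Cacna1i, a low-voltage calcium channel, was higher in VTA (-2.15), as were the pacemaking channel Cacna1d (-0.72) and the sodium channel Scn8a (-0.87), and the last 2 calls ended with the correction. Calcium buffering and clearance genes were split, with 7 of 30 higher in SNpc and 8 in VTA, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.970). The calcium sensor Vsnl1 rose in SNpc to 5371 ± 555 CPM from 2209 ± 315 (1.28), and the inositol trisphosphate receptor Itpr1 was higher in VTA (-1.10).

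**Figure D4:**
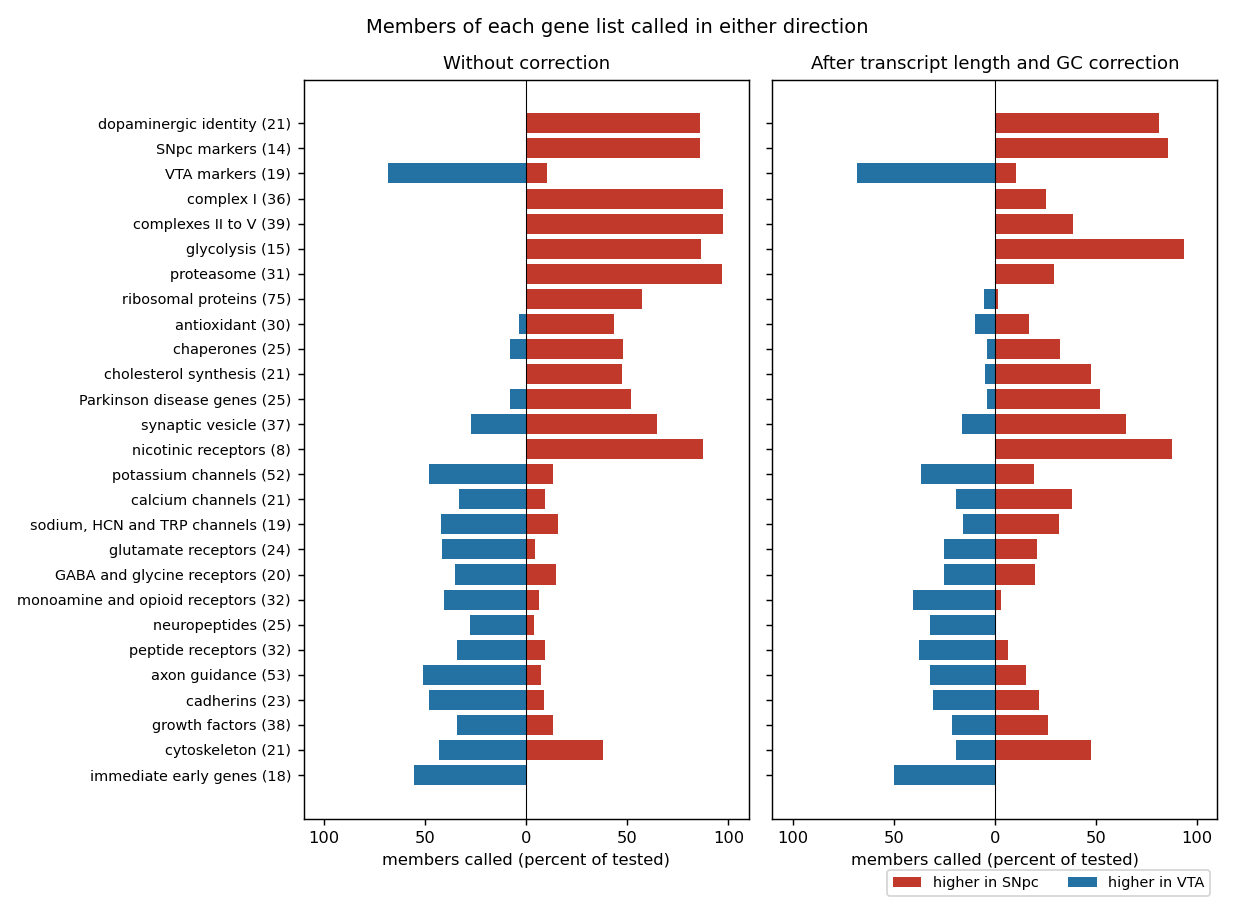
Percent of the tested members of each list (number in brackets) called higher in SNpc (red, to the right) or in VTA (blue, to the left), without correction and after the length and GC correction with the library scale kept. Respiratory chain, proteasome and ribosomal protein bars shrink with the correction, while those of dopaminergic identity, SNpc markers, glycolysis and nicotinic receptors change little.

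Axon guidance and adhesion genes that passed were more often higher in VTA than in SNpc. Of 53 axon guidance genes, 27 were higher in VTA and 4 in SNpc, or 28 and 5 adjusted over the list alone, with a median of -0.80 (camera adjusted p = 2.99e-05, adjusted p = 0.139 with an estimated correlation). The semaphorin receptors Nrp2 (-1.97) and Plxnc1 (-1.15) were among them. Of 23 cadherins and protocadherins, 11 were higher in VTA and 2 in SNpc, or 12 and 3 adjusted over the list alone (median -0.36, camera adjusted p = 0.0458, adjusted p = 0.253 with an estimated correlation), including Pcdh9 (-1.21) and Cdh2 (-0.86). After the length and GC correction, 17 guidance genes and 7 cadherins were higher in VTA and 8 and 5 in SNpc. With the scale refitted 14 and 6 were higher in VTA and 11 and 7 in SNpc, and neither list was called in either version. The cadherin call was also lost without SNpc library 3 or without VTA library 1, 4 or 6. Axonal cytoskeleton genes were split without correction, 9 of 21 in VTA and 8 in SNpc, or 10 and 8 adjusted over the list alone (camera adjusted p = 0.505). After the length and GC correction 10 were higher in SNpc and 4 in VTA (14 and 4 with the scale refitted), and their median turned from -0.27 to 0.26. Heavy neurofilament Nefh (-1.44) and the axon initial segment organiser Ank3 (-1.65) were higher in VTA. Of 38 growth factor genes, 13 were higher in VTA and 5 in SNpc, the same adjusted over the list alone (camera adjusted p = 0.298), with Vegfa at -1.11 and the GDNF receptor Ret at 0.67. Both versions of the correction turned this to 10 in SNpc and 8 in VTA.

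Stress and disease genes that passed were more often higher in SNpc, though fewer passed with glial markers as a covariate. Of 25 genes linked to parkinsonism, 13 were higher in SNpc and 2 in VTA, or 15 and 2 adjusted over the list alone (median 0.32, camera adjusted p = 0.00702, adjusted p = 0.253 with an estimated correlation). Uchl1, a ubiquitin hydrolase, changed by 0.71, and Vps13c, a lipid transfer protein, by -0.93, although the latter call ended with the correction for length alone. Of 30 antioxidant genes, 13 were higher in SNpc and 1 in VTA, or 15 and 1 adjusted over the list alone (median 0.36, camera adjusted p = 0.0017, adjusted p = 0.384 with an estimated correlation). Mitochondrial superoxide dismutase Sod2 changed by 0.48 and secreted Gpx3 by -1.21, and the list's call ended with the length and GC correction, which gave 5 in SNpc and 3 in VTA (10 and 1 with the scale refitted). Chaperone and unfolded protein response genes gave 12 of 25 higher in SNpc and 2 in VTA, or 13 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.0017, adjusted p = 0.253 with an estimated correlation), with Hspa8 at 0.55. Cholesterol synthesis gave 10 of 21 higher in SNpc and 0 in VTA, the same adjusted over the list alone (median 0.33, camera adjusted p = 0.0033, adjusted p = 0.383 with an estimated correlation), but 6 without SNpc library 1 or 6. With glial markers as a covariate the genes higher in SNpc fell to 8 of the parkinsonism list, 7 antioxidant, 7 chaperone and 4 cholesterol synthesis genes. Immediate early genes, which neuronal activity and dissection induce, were higher in VTA, 10 of 18 and 0 in SNpc, the same adjusted over the list alone (median -1.07, camera adjusted p = 2.33e-04, adjusted p = 0.139 with an estimated correlation). Nr4a1 changed by -2.04 and Egr1 by -1.80.

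Of the 40 lists, 21 were called by camera with the preset correlation. With an estimated correlation camera called 0 lists, 5 of them at an unadjusted p under 0.05, and fry called 33. The list calls therefore rest on the preset correlation. Counts of members do not use it, but members of some lists vary together, with estimated correlations up to 0.872. Such members are not independent evidence. The counts are to be read against all 15685 genes tested, of which 2793 were higher in SNpc and 3203 in VTA. Counts of 5 or fewer members changed by up to 3 genes when 1 library was left out, and more for the oligodendrocyte markers given below.

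Markers of other cells were present in both groups and some moved with the region. Of 12 astrocyte markers, 4 were higher in VTA and 0 in SNpc (camera adjusted p = 0.114), with the glutamate transporter Slc1a2 at 470 ± 49.0 CPM in VTA and 276 ± 51.5 in SNpc (log2 fold change -0.77), a call that ended with the length correction. Fgfr3 changed by -1.30, and Aldoc did not differ beyond the spread (0.05 ± 0.12 SE, edgeR adjusted p = 0.748). Oligodendrocyte precursors had 4 of 7 markers higher in VTA (camera adjusted p = 0.113), Pdgfra (-1.13) and Olig2 (-1.18) included, and oligodendrocytes 1 of 13 (camera adjusted p = 0.399), Ugt8a (-1.10), with Mbp at -0.70 ± 0.43 (SE, edgeR adjusted p = 0.233). The calls of Fgfr3 and Pdgfra ended with glial markers as a covariate and with the refitted length and GC correction. Both genes are themselves part of that covariate, so its effect on their calls decides nothing. Without SNpc library 4, which held the most astrocyte and oligodendrocyte RNA of the SNpc libraries, these 3 lists were called higher in VTA, with 7, 5 and 7 members.

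Microglial markers gave 2 of 12 higher in VTA and 1 in SNpc (camera adjusted p = 0.853), with P2ry12 at -0.89, and vascular markers 3 of 11 in VTA (camera adjusted p = 0.235), with the pericyte gene Pdgfrb at -2.86. Without VTA library 1, which held the most vascular RNA, 1 vascular marker was called and the list's median went from -1.83 to -0.21. With the glial covariate 1 was called as well. Glutamatergic markers gave 4 of 8 in VTA and 0 in SNpc (median -1.73, camera adjusted p = 0.0465, adjusted p = 0.305 with an estimated correlation). Slc17a6, the vesicular glutamate transporter and also in the VTA marker list, was 93.4 ± 16.8 CPM in VTA and 36.1 ± 21.7 in SNpc. The glutamatergic call ended with library totals as the scale, with the glial covariate (2 members left) and without any one of SNpc libraries 3 and 6 or VTA libraries 1 and 4. GABAergic markers gave 1 of 11 higher in SNpc and 0 in VTA (camera adjusted p = 0.740), with a median of -0.01 and a mean of -0.05 although camera placed the list on the SNpc side, where 4 were called with the glial covariate. That median was above 0 without any one of SNpc libraries 1, 2 and 3 or VTA libraries 2 and 4. Without SNpc library 4 it fell to -0.55, with 2 GABAergic markers called higher in VTA and 1 in SNpc. Serotonergic markers gave 1 of 5 in VTA (Htr1a, -1.36, camera adjusted p = 0.217), hypothalamic markers 3 of 10 in VTA (Foxp2, -0.75, among them, camera adjusted p = 0.294), or 6 without VTA library 4, and ependymal markers 0 of 5 in either region (camera adjusted p = 0.853). Of 4 cholinergic markers 2 were higher in SNpc, Chat (1.42) and Prph (1.66), at 3.43 and 3.91 CPM (camera adjusted p = 0.273), and both calls ended with the glial covariate, that of Chat also without SNpc library 6. The call of Htr1a ended with the glial covariate as well. Adjusted over the list alone, all these lists gave the same counts except the microglial one, with 1 in VTA and 1 in SNpc.

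Of 15 library measures, 4 differed (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0298). SNpc libraries had fewer genes with a count (16835 ± 245 against 17730 ± 499, n = 5) and a higher share of counts in the 100 most abundant genes (23.2% ± 1.33 against 19.4% ± 0.195). Mean log2 CPM was lower in SNpc for oligodendrocyte precursor markers (2.30 against 3.29) and glutamatergic markers (-0.83 against 1.45). Astrocyte markers, at 3.06 against 3.84, did not pass (exact permutation p = 0.0476, adjusted p = 0.119). Without VTA library 5 or VTA library 6, 0 measures passed the adjusted test.

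**Figure D5:**
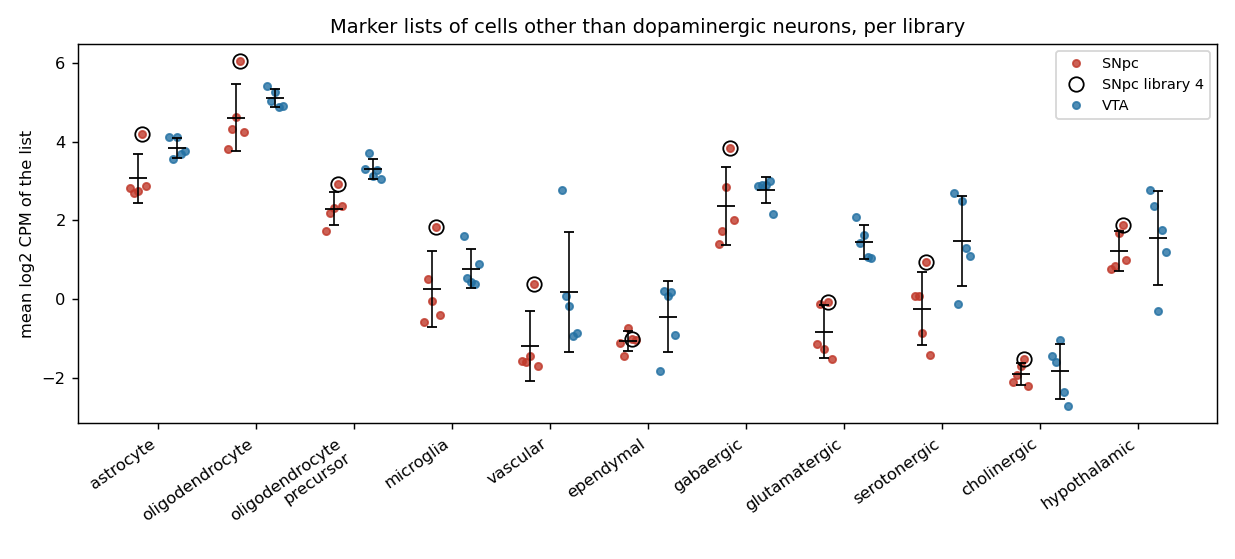
Mean log2 CPM of each marker list of other cell types in the 5 SNpc (red) and 5 VTA (blue) libraries, with bars for the mean and SD and a ring around SNpc library 4. SNpc library 4 is the highest SNpc library in 10 of the 11 lists.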

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

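The 3 tests on SNpc library 4 were chosen only after the results had been seen. Single libraries far from the other 4 of their region were sought by Dixon's test in 260 sets of values, and 18 stood apart at the 95% level. Chance alone marks about 1 in 20.

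SNpc library 4 accounted for 9 of the 18. Malat1, a nuclear noncoding RNA, stood at 1872 CPM there against 86.3 to 223 in the other SNpc libraries, and Meg3, another, at 350.4 against 41.1 to 84.7. The oligodendrocyte gene Mbp was at 360 CPM against 77.4 to 122, and the astrocyte genes Aldoc and Fgfr3 were at 268 and 5.66 CPM against 165 to 185 and 1.65 to 2.10. Slc17a6 was at 73.3 CPM against 17.3 to 32.9, and the SNpc marker Serpine2 was lower there, at 221 CPM against 298 to 305. The mean log2 CPM of the astrocyte list was 4.18 against 2.68 to 2.87, and that of the vascular list 0.37 against -1.70 to -1.45.

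A VTA library under an SNpc label was argued against, since on an axis of regional markers from the other SNpc libraries at 0 to the VTA libraries at 1 the library lay at 0.183. More RNA of other cells remained open, since 10 of the 11 marker lists of other cells had their highest SNpc mean in this library. More nuclear RNA remained open beside it, since the mean of the nuclear noncoding RNAs was 6.43 on the log2 scale, 1.37 above the next SNpc library, while the other 4 spanned 0.946. Not all members took part, since Rian (249.9 CPM against 177 to 282) and Kcnq1ot1 (5.34 against 2.23 to 5.63) lay within the other SNpc libraries. The mean of this library was also above those of the VTA libraries, 5.60 to 6.28, so both may have come with this dissection or purification. The design gives no factor that sets this library apart, so no biological explanation was tested.

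The other libraries that stood apart are given as values. In VTA library 2, Satb1 was at 230.8 CPM against 289 to 309, Ret at 511 against 710 to 782, Pclo at 475 against 288 to 340 and the noncoding RNA Rian at 1178 against 621 to 753. In VTA library 1, Nfix was at 116 CPM against 65.5 to 79.0, and the mean log2 CPM of the vascular list was 2.77 against -0.95 to 0.09. In VTA library 6 the mean of the GABAergic list was 2.16 against 2.88 to 2.99. In SNpc library 1, Srpx2 was at 27.1 CPM against 8.70 to 13.95, and in SNpc library 6, Cox5a was at 384 CPM against 430.0 to 448.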

How the results depend on the processing

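The length corrections, the 12 columns as deposited and the removal of SNpc library 4 together with VTA library 1 were chosen after the results were seen. The number of genes differing between SNpc and VTA, 5996, was 6640 with DESeq2, 6303 with limma-voom, 5809 to 6143 with other scalings, 5933 and 6059 with other filters, 5998 after thinning, 7247 with all 12 columns, 4881 and 4821 after the length and the length and GC correction and 5636 with the scale refitted. The length and GC correction shared 3814 calls with the uncorrected fit and turned 20 of the genes called in both fits. Leaving out 1 library gave 5074 to 6510 genes differing between SNpc and VTA, 2284 to 3317 genes higher in SNpc and 2790 to 3193 genes higher in VTA. Against a 1.5-fold change, 1240 passed, 94 genes higher in SNpc and 1146 genes higher in VTA. With the glial covariate there were 1798 genes higher in SNpc, and with the refitted length and GC correction 2050 genes higher in VTA. The cause was not tested.

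A correlation over 0.1 between the deviations of every same-numbered pair was sought as a sign of pairing by replicate number. Paired libraries need not reach it, so lower values do not exclude pairing. Correlations were 0.0371 for number 1, -0.124 for 2, -0.00237 for 4, -0.177 for 5 and -0.0124 for 6. Number 3 gave 0.127, the highest of all, but VTA 3 is identical to VTA 2, as SNpc 5 is to SNpc 4. With the number as a replicate block, under the 4 numberings that the identical columns allow, genes differing between SNpc and VTA numbered 4385 to 4688, with 1814 and 1826 genes higher in SNpc under the numberings that used VTA 2. With block and glial covariate together they were 1339, 1826, 1934 and 2433. Of these, 170, 381, 366 and 639 were genes higher in SNpc and 1169, 1445, 1568 and 1794 genes higher in VTA. The cause was not tested, but that fit has few residual degrees of freedom.

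Of the gene lists differing between SNpc and VTA (21), an estimated correlation left 0 and fry called 33. Leaving out 1 library gave 18 to 26, with 26 without SNpc library 4. The ribosomal_proteins list turned to VTA under the length and GC correction (camera adjusted p = 0.762) and the cadherins_adhesion list to SNpc with the scale refitted (camera adjusted p = 0.953), neither called, with adjusted p over the alternatives, fry included, of 3.84e-13 to 0.762 and 2.15e-04 to 0.953. Library-level measures between SNpc and VTA that passed numbered 0 to 6 when 1 library was left out. Malat1 (0.19, not called) ran from -1.53 without SNpc library 4 to 0.46 without SNpc library 1, and was -1.28 without SNpc library 4 and VTA library 1. In the simulation 1.5-fold changes were recovered in 26.9% of cases, but it gave 129 calls, far fewer than the real data. That rate need not hold here, and a gene not called may still differ by that much.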

Other observations

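The lists of hedgehog, nuclear factor I and nuclear noncoding RNA genes were written only after results had been seen. The comparison of astrocyte with GABAergic markers and that over all 11 lists of other cells were also chosen then. So were the test of length slopes at equal total counts and the length correction with the library scale kept.

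Of 11 genes of hedgehog signalling, 7 were higher in VTA and 0 in SNpc, the same adjusted over the list alone, with a median log2 fold change of -1.48 (unadjusted camera p = 1.18e-05, p = 0.00898 with an estimated correlation). The receptor Ptch1 was 391 ± 49.1 CPM in VTA and 99.8 ± 9.82 in SNpc (log2 fold change -1.97), and Smo, the signal transducer, 7.84 ± 0.423 against 1.67 ± 0.997 CPM (-2.23). Gli1 (-0.64) and Hhip (-0.67), targets of the pathway like Ptch1, were not called (edgeR adjusted p = 0.568 and 0.261), nor were Sufu and Boc. All 4 nuclear factor I genes, regulators of glial and neuronal differentiation, were higher in VTA, with log2 fold changes of -1.87 for Nfia, -2.19 for Nfib, -1.76 for Nfic and -1.72 for Nfix (camera p = 1.84e-11, p = 0.00116 with an estimated correlation). After the length and GC correction with the library scale kept 6 hedgehog genes, 5 of them called before it, and the 4 nuclear factor I genes were higher in VTA. Both groups were noticed in the results and then tested on them, so the p-values describe these libraries and are no independent evidence. Glia express several of these genes too.

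Whether nuclear noncoding RNAs moved with the region rested on SNpc library 4. With it, 2 of 7 were higher in VTA (median -0.54, unadjusted camera p = 0.0450, p = 0.359 with an estimated correlation). This list too was added after results had been seen, so its p-values are no independent evidence. Rian was 779 ± 229 CPM in VTA and 226 ± 42.7 in SNpc, whereas Malat1 (0.19) and Meg3 (-0.54) were not called. Without SNpc library 4, 5 of the 7 were higher in VTA, the median was -1.37 and Malat1 turned to -1.53.

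Longer transcripts were higher in VTA, while respiratory chain and proteasome genes were higher in SNpc. Thinning to 1 total decided nothing about library depth, since rho between transcript length and log2 fold change was -0.473 before and after it, but depth as the whole cause was argued against by the libraries' length slopes, which at equal total counts still differed by 0.302 ± 0.0537 (SE) log2 CPM per doubling of length between VTA and SNpc. Whether a length and GC trend accounts for the whole respiratory chain and proteasome change cannot be told apart, because 103 of 106 genes were called before correction, 33 (31.1%) after it with the library scale kept and 71 (67.0%) with the scale refitted, and their median fell from 0.60 to 0.19 or 0.33. The excess of these genes over the median of all genes fell from 0.64 to 0.24 in both versions and camera with the preset correlation called all 3 lists in both, so part of the difference may be a length trend from amplification, and a regional difference in these genes stays open beside it. Unspliced nuclear RNA in VTA cannot be told apart either, since the partial rho of genomic span at fixed length, -0.104, ran from -0.115 to -0.0893 without single libraries, around the bound of -0.1.

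Dopaminergic identity genes were higher in SNpc, while several markers of other cells were higher in VTA. The amount of glial RNA as the whole cause was argued against, so far as the mean of glial markers tracks it. With glial markers as a covariate the median of the dopaminergic list was 0.55 (0.548) against 0.68 without and 14 of its 21 genes were still called. The marker mean is an imperfect measure of glial RNA, so it may correct too little. A lower share of dopaminergic RNA in VTA would raise all other cell types alike only if both regions had the same neighbouring cells. The mean log2 CPM of all 11 lists was lower in SNpc, the direction that such a lower share predicts. Differences (SNpc minus VTA) ran from -2.28 for glutamatergic to -0.06 for cholinergic markers. Each library's mean over the lists was then removed, which takes out a common rise. The remaining regional differences of the 11 lists spread with an SD of 0.669, more than under other arrangements of the libraries (exact permutation p = 0.0159, or 0.0238 over the 8 lists with a mean of at least 1 CPM). This spread argues against an equal rise of all lists, but not against a common rise with unequal sizes or a lower share among neighbours that differ. Astrocyte and GABAergic markers alone differed by -0.37 in their regional change (exact permutation p = 0.278), which decides nothing. A lower dopaminergic share in VTA, a change in which other cells were captured and higher expression of these genes in SNpc neurons may all be at work. The glutamatergic list holds Slc17a6, which VTA dopaminergic neurons express.

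Other arrangements of the 10 libraries into groups of 5 were tried, 100 in all with the real one. The real arrangement gave 5996 genes and the highest other 14, and only the real 1 of the 100 reached that count. So many genes are thus unlikely from a chance split of these libraries, but with 126 possible arrangements chance is not excluded. Every other arrangement mixed the regions, which widens the spread within its groups. For the number of lists chance remained open, since 20 of the 100 arrangements gave at least the real 21 lists and the highest other gave 30.

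VTA libraries differed among themselves in some of the genes with the largest changes. Across them Rai1 ran from 663 CPM in library 1 to 3209 in library 2, Jmjd1c from 1061 to 3342 and Prr12 from 832 to 1920, each with its highest value in VTA library 2. Cerkl (chromosome 2, 79332491 to 79428988) and Neurod1 (79452637 to 79456636), both among the 10 largest VTA changes, lie side by side in the genome, with log2 fold changes of -2.88 and -2.81. Their CPM was close in most libraries, such as 40.7 and 38.3 in VTA library 2, and less so in VTA library 1 (18.8 and 13.1). Whether they share reads was not tested, so they may not be 2 separate changes. Of 4 tested transcripts that differ between the sexes, 1 was higher in VTA and 0 in SNpc, the same adjusted over the list alone (camera adjusted p = 0.652). All 4 lie on chromosome Y and had counts in every library. The 1 called was Uty (-0.88), whereas Ddx3y, the most abundant, was at 57.7 CPM in SNpc and 57.9 in VTA. Kdm5d (-0.39) and Eif2s3y (0.32) were not called.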
